A study of Homo sapiens with 16 samples.

How the data were processed

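The values used were counts of reads per gene as deposited by the authors, 1 column for each of 16 libraries and 23228 gene symbols. Per the labels' protocols, RNA was extracted with RNeasy columns, libraries were made with a TruSeq total RNA kit, and 100-bp single-end reads were sequenced. Per the submitters' processing notes, base calls were made with CASAVA 1.8.2, reads were aligned to hg19 with TopHat2 2.0.8b, and reads on genes were counted with HTSeq. The HTSeq version, the gene annotation and the strand setting are not given in the sources used here, so genes that overlap or have antisense partners are uncertain. Reads that named no gene stayed out of library sizes and tests: 7.662 to 8.757% of all counted alignments had no feature, 1.115 to 1.266% were ambiguous and 23.679 to 25.57% were not unique. A GRCh38 gene table served only for names, biotypes, lengths, GC content and genomic spans. It matched 20057 symbols by current name and 1835 by 1 older name, and 1336 were not matched.

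Of 19088 genes with a read, 13980 passed edgeR's filterByExpr (minimum count 10) and were tested. Counts were scaled by TMM factors (0.9617 to 1.0469) and fitted in R 4.3.3 with edgeR 4.0.16, with a robust quasi-likelihood fit, 1 coefficient per group over all 16 libraries and 8 residual degrees of freedom. The 14 comparisons were the effects of MMS and sorafenib alone at each time, each effect in the presence of the other agent, their interaction at each time, the mean MMS effect at each time, the change of the MMS effect with time and the change of controls with time. Genes with Benjamini-Hochberg adjusted p under 0.05 were called. Gene lists (26, written from general knowledge) were tested by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists of a comparison. They covered p53, ATF4, ER chaperone, heat shock, NRF2, ERK output, immediate early, cholesterol, fatty acid, hypoxia, NF-kB and interferon genes. They also covered G1/S, G2/M, histone, base excision, homologous recombination, other repair, BCL2 family, autophagy, ribosomal protein, respiratory chain and matrix genes and markers of blood, fibroblast and luminal cells. Some genes belonged to more than 1 list, so calls of lists that share members are not independent. Groups, comparisons, lists and alternatives were chosen before the data were examined.

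Genes were named by rule: the 8 called genes with the largest rise and fall in each of the 4 effects of a single agent and 4 per direction elsewhere, with the same sign in both cultures and a mean of at least 2 CPM in the higher group. Clones, open reading frames, pseudogenes and small RNAs were passed over. From each list up to 4 called members of smallest p were eligible, or the member of smallest p where only the list passed. ATF3, DDIT3, CDKN1A, MDM2, DUSP6, HMGCS1, HMOX1, IL6, MGMT and MPG were always tested for naming. The text prints a part of these. Alternatives were RLE size factors, scaling by total counts, no filter beyond 1 read, DESeq2 1.42.0, the culture as a block, only the libraries of the groups compared, the sequencing lane as an additive term (3 residual degrees of freedom) and leaving out each library. For lists they were an estimated correlation, fry and the block. The replicate number marked the culture: deviations of replicate 2 from replicate 1 correlated between all 28 pairs of groups (0.492 to 0.71, median 0.641), so results are also given with that block (7 residual degrees of freedom).

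In a self-test, counts were simulated for each gene independently and with no culture effect. A known share of genes was raised or lowered before the 8 h MMS test. The edgeR test recovered 20 of 65 genes changed 1.5-fold, 40 of 64 changed 2-fold and 55 of 64 changed 4-fold. It made 122 calls, of which 7 were false, and 0 calls when no gene was changed. Camera called a list of 30 raised genes and did not call a list of 30 unchanged genes, and a true slope of 1.3 was returned as 1.27. As simulated genes did not move together, the self-test cannot show how camera behaves on lists of correlated genes. Python 3.11.15 and matplotlib 3.10.9 were used for tables and drawings.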

Results

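RNA was sequenced from MDA-MB-231 cells, an established line from a triple-negative breast cancer. The cells had been exposed to methyl methanesulfonate (MMS), an agent that methylates DNA bases and other cell constituents, with or without sorafenib, a kinase inhibitor whose targets include the RAF kinases upstream of ERK. MMS was given at 40 µg/mL, and RNA was taken 8 or 24 h after it was added. Sorafenib was given for 24 h before MMS and kept in the medium, so all times below count from the start of MMS and not from that of sorafenib. Its dose is one that the study's design text gives as 5 µM and its treatment protocol as 1 µM, and it is left open here. The 8 groups (neither agent, MMS, sorafenib or both, at each time) held 2 libraries each, 1 from each of 2 independent cultures. Libraries held 16.8 to 26.5 M reads on genes (median 20.4 M), and 13980 genes had enough reads to be tested. Effects below are log2 fold changes ± standard error from edgeR's quasi-likelihood test with n = 2 cultures per group, levels are mean CPM (counts scaled by library size) ± SD, and adjusted p values are Benjamini-Hochberg adjusted. Sequencing lanes were not balanced over the groups. The 8 h and 24 h controls shared no lane, nor did the 8 h groups given MMS alone and both agents. At 8 h no lane held both an MMS-treated and an untreated library, and at 24 h lanes that held both had them from different cultures, so no MMS-treated and untreated library of the same culture could be compared within a lane.

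The response to MMS alone at 8 h was led by stress genes. ATF3, a transcription factor induced by many stresses, rose from 7.74 ± 1.08 to 87.2 ± 1.25 CPM (3.48 ± 0.23). CHAC1, an enzyme that degrades glutathione, rose by 3.26 ± 0.34, and HMOX1, the heme-degrading enzyme heme oxygenase 1, by 3.26 ± 0.21. Among the genes that fell were the chemokine gene CCL2 (-4.12 ± 0.72), the cAMP phosphodiesterase gene PDE4B (-4.09 ± 0.24). SMAD6, an inhibitor of BMP signalling, fell too (-2.99 ± 0.29). The largest fitted rise was that of the heat shock gene HSPA6 (4.87 ± 0.74), from 0.166 ± 0.0601 to 5.17 ± 2.64 CPM. The cell-cycle inhibitor gene CDKN1A had 1.48 ± 0.54 with adjusted p = 0.0754, and 5.52e-08 with the culture as a block. MDM2, which encodes the p53 ubiquitin ligase, rose by 0.41 ± 0.08, and the glycosylase gene MPG, whose product removes methylated purines, had -0.21 ± 0.18 (adjusted p = 0.433). HMGCS1, an enzyme of cholesterol synthesis, had 0.43 ± 0.17 (adjusted p = 0.0821, and 0.0221 with the block). The methyltransferase gene MGMT had at most 1 read in any library and was not tested.

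By group, 30 of 36 tested ATF4 and integrated stress response genes rose at 8 h (32 adjusted over the list alone). Their median was 1.14 (camera adjusted p = 7.62e-35, adjusted p = 0.0127 with an estimated correlation). Genes that rose included SESN2, a regulator of amino acid sensing (3 ± 0.12), TRIB3, an inhibitory partner of ATF4 and AKT (2.41 ± 0.14), and DDIT3, which encodes the factor CHOP (2.07 ± 0.17). Of 24 ER chaperone genes of the unfolded protein response, 15 rose (19 rose and 1 fell adjusted over the list alone; camera adjusted p = 5.74e-15, adjusted p = 0.0573 with an estimated correlation). HSPA5, the main chaperone of the endoplasmic reticulum, went from 850 ± 73 to 2930 ± 174 CPM (1.79 ± 0.12), and DNAJB9, a co-chaperone of that compartment, rose by 1.72 ± 0.12. Of 28 NRF2 targets, 15 rose (17 adjusted over the list alone), among them TXNRD1, which encodes thioredoxin reductase (2.10 ± 0.13), and NQO1, a quinone reductase gene (1.73 ± 0.11). The NRF2 list had camera adjusted p = 5.1e-19, and 0.0127 with an estimated correlation. Heat shock genes rose in 8 of 24 cases and fell in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.00398, adjusted p = 0.0739 with an estimated correlation). HSPA1A (1.11 ± 0.12) and HSPA1B (0.85 ± 0.12) were among them. They are near-identical copies that share reads, so their separate values are uncertain. In the p53 target list 12 genes rose, 1 fell and 20 did not pass (13 and 1 adjusted over the list alone). Its camera adjusted p was 0.00012, and 0.0127 with an estimated correlation. GADD45A, a growth arrest gene, rose by 2.16 ± 0.17, and PMAIP1, which encodes the death-promoting protein NOXA, by 0.60 ± 0.08. Immediate early genes rose in 16 of 30 cases, such as FOS (2.62 ± 0.30) and DUSP1 (1.93 ± 0.16), and 1 fell (16 and 1 adjusted over the list alone; camera adjusted p = 2.09e-08, adjusted p = 0.0971 with an estimated correlation).

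Genes of mitosis fell as a group at 8 h: 33 of 43 tested G2/M genes fell (36 adjusted over the list alone), with a median of -0.54 (camera adjusted p = 1.26e-19, adjusted p = 0.0739 with an estimated correlation). TOP2A, the topoisomerase of dividing cells, fell from 905 ± 97.2 to 304 ± 6.23 CPM (-1.58 ± 0.14), and the mitotic kinase gene PLK1 also fell (-1.27 ± 0.12). Of 23 genes that report ERK activity, 10 fell and 3 rose (12 and 3 adjusted over the list alone). The ERK list had camera adjusted p = 1.05e-05, and 0.0374 with an estimated correlation. CCND1, which encodes cyclin D1 (-1.30 ± 0.09), and the ERK phosphatase gene DUSP6 (-1.30 ± 0.10) fell. Extracellular matrix genes fell in 11 of 35 cases and rose in 2 (14 and 2 adjusted over the list alone), with THBS1 at -1.65 ± 0.12. The matrix list had camera adjusted p = 0.000246, and 0.0153 with an estimated correlation. The autophagy and lysosome list had 10 genes that rose and 3 that fell (10 and 4 adjusted over the list alone; camera adjusted p = 0.0122, adjusted p = 0.184 with an estimated correlation). Its cargo receptor gene SQSTM1 rose by 1.21 ± 0.10. NF-kB and cytokine genes went both ways, with 8 higher, 7 lower and no list call (9 and 9 adjusted over the list alone; camera adjusted p = 0.905). The median (0.16) and mean (0.17) of that list lay above 0 while camera's direction was down. The neutrophil chemokine gene CXCL2 rose by 2.33 ± 0.24, IL6 by 0.76 ± 0.21, and the NF-kB inhibitor gene NFKBIA fell (-1.57 ± 0.09). Among the 26 lists, 10 passed camera's test at 8 h, of which 5 passed with an estimated correlation.

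In all, MMS at 8 h changed 3700 of 13980 genes, 1878 higher and 1822 lower, and 315 rose and 471 fell by at least 2-fold. With the culture as a block the count was 6100, and with the lane as an additive term edgeR called 0 genes (816 at unadjusted p under 0.05). Of the 3700 genes 98.2% kept their sign with that term, and the median standard error went from 0.148 to 0.411. The count was 2372 without replicate 1 of the 8 h control group and 2466 without replicate 1 of the 8 h MMS group.

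**Figure D1:**
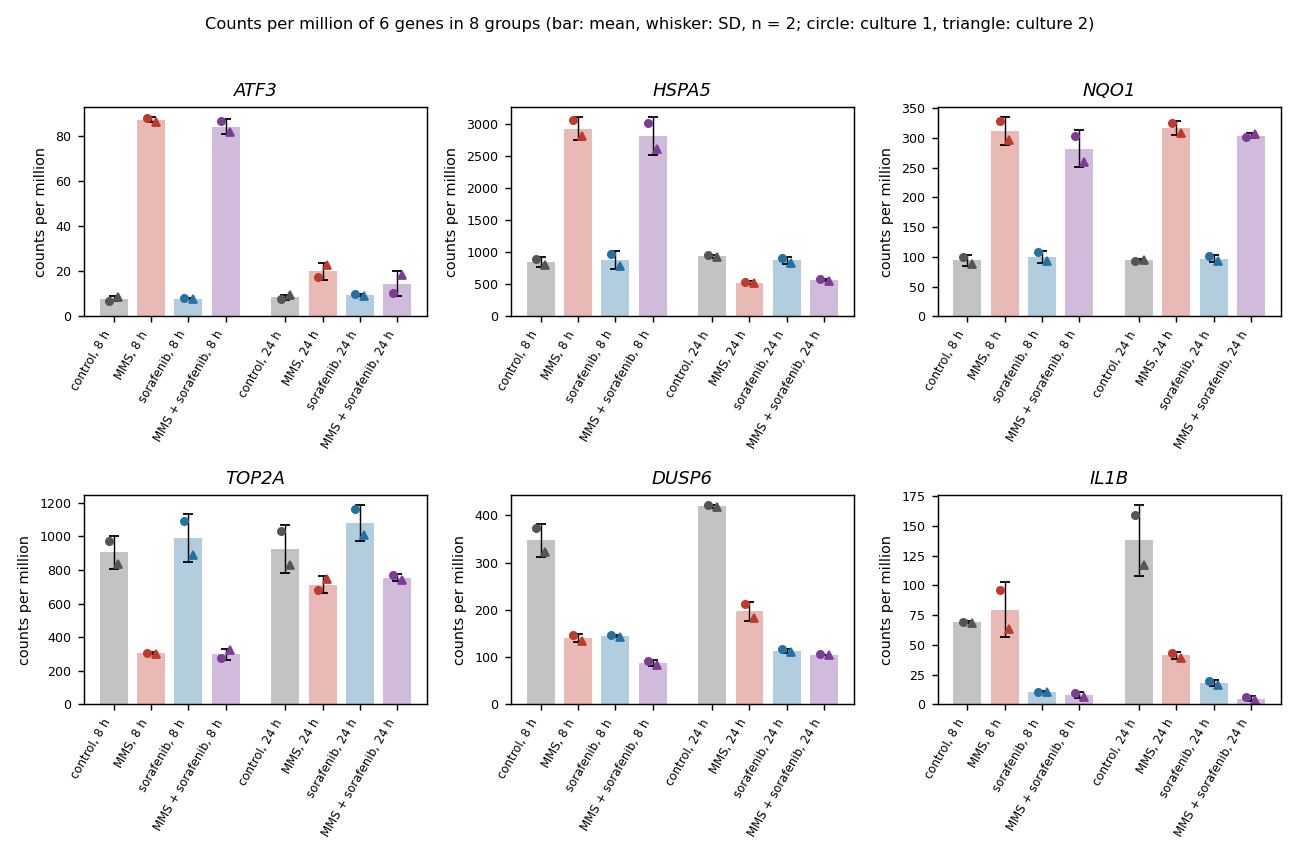
CPM (vertical) of 6 genes in the 8 groups (horizontal), with bars for the mean, whiskers for the SD and 1 point for each of the 2 cultures. ATF3 stood at 87.2 ± 1.25 CPM (SD, n = 2) after 8 h of MMS and at 20 ± 3.74 CPM after 24 h, against 7.74 ± 1.08 and 8.4 ± 1.23 CPM in the controls.

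After 24 h of MMS alone the oxidative stress gene NQO1 was still high, while the ER chaperone gene HSPA5 lay below the control level. NQO1 stood at 317 ± 11.6 CPM against 94.6 ± 1.35 in controls (1.75 ± 0.11), and FTL, which encodes the ferritin light chain and has processed pseudogenes that can take its reads, rose by 1.71 ± 0.15. HSPA5 stood at 527 ± 17.6 against 940 ± 23.1 CPM (-0.83 ± 0.11), and HMOX1 had 0.40 ± 0.21 (adjusted p = 0.165). The largest rises were those of ARC, an immediate early gene (5.15 ± 0.57), HSPA6 (4.38 ± 0.70) and the stromelysin gene MMP3 (3.49 ± 0.45). The largest falls were those of the mucin gene MUC5B (-5.76 ± 1.20), the NADPH oxidase gene NOX5 (-4.60 ± 0.42) and AGR2, a disulfide isomerase of secretory cells (-4.59 ± 1.39). CDKN1A had 0.32 ± 0.54 (adjusted p = 0.692, and 0.0313 with the culture as a block), and DDIT3 had 0.43 ± 0.17 (adjusted p = 0.078, and 0.0216 with the block). ATF3 (1.25 ± 0.22) and MDM2 (0.57 ± 0.08) rose, HMGCS1 had -0.41 ± 0.17 (adjusted p = 0.0882, block 0.0317), and MPG had -0.45 ± 0.18 (adjusted p = 0.0729, block 0.0132).

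Genes of DNA synthesis and homologous recombination rose at 24 h while genes of mitosis fell. Of 35 homologous recombination and Fanconi genes, 21 rose (23 adjusted over the list alone; camera adjusted p = 3.49e-06, adjusted p = 0.184 with an estimated correlation). The strand exchange genes XRCC3 (0.90 ± 0.09) and RAD51C (0.75 ± 0.11) were among them. Of 35 G1/S and DNA replication genes, 18 rose and 4 fell (21 and 5 adjusted over the list alone; camera adjusted p = 1.61e-05, adjusted p = 0.184 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, rose by 1.06 ± 0.08 and the licensing factor gene CDT1 by 0.90 ± 0.11. Of 43 G2/M genes, 29 fell (30 fell and 1 rose adjusted over the list alone; camera adjusted p = 7.55e-11, adjusted p = 0.184 with an estimated correlation). The mitotic kinesin gene KIF20A had -1.26 ± 0.12. In the base excision and direct repair list 8 genes rose, such as ALKBH1 (0.97 ± 0.12), and 3 fell, such as XRCC1 (-0.71 ± 0.11). That list had camera adjusted p = 0.0566, and 0.0327 with the culture as a block (9 and 3 adjusted over the list alone). The nucleotide excision, mismatch and translesion list had 6 genes higher and 1 lower (6 higher adjusted over the list alone; camera adjusted p = 0.104), with the translesion ubiquitin ligase gene RAD18 at 0.69 ± 0.10. ATF4 list genes rose in 17 of 36 cases and fell in 1 (20 and 1 adjusted over the list alone; camera adjusted p = 1.61e-05, adjusted p = 0.184 with an estimated correlation). The gene that fell was DDIT4, an inhibitor of mTORC1 (-2.41 ± 0.22). The p53 target list did not pass at 24 h (9 higher and 3 lower of 33, 10 and 3 adjusted over the list alone, camera adjusted p = 0.269). Heat shock genes rose in 7 of 24 cases and fell in 1 (7 and 1 adjusted over the list alone; camera adjusted p = 0.0137, adjusted p = 0.153 with an estimated correlation). NRF2 targets rose in 10 of 28 cases and fell in 3 (11 and 3 adjusted over the list alone; camera adjusted p = 0.0008, adjusted p = 0.184 with an estimated correlation).

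Part of the hypoxia, interferon, cytokine, fatty acid and matrix genes fell at 24 h. Hypoxia and glycolysis genes fell in 15 of 30 cases and rose in 1 (18 and 1 adjusted over the list alone; camera adjusted p = 1.01e-06, adjusted p = 0.153 with an estimated correlation). They included the carbonic anhydrase gene CA12 (-2.36 ± 0.17) and LDHA, which encodes lactate dehydrogenase A (-0.87 ± 0.07). Interferon-stimulated genes fell in 13 of 34 cases (13 adjusted over the list alone; camera adjusted p = 0.00014, adjusted p = 0.153 with an estimated correlation). The antiviral genes IFIT2 (-1.57 ± 0.15) and OASL (-2.36 ± 0.27) were among them. NF-kB and cytokine genes fell in 12 of 31 cases and rose in 1 (15 and 1 adjusted over the list alone; camera adjusted p = 0.0008, adjusted p = 0.153 with an estimated correlation). The interleukin genes IL1B (-1.73 ± 0.26) and IL6 (-0.74 ± 0.21) fell. Fatty acid synthesis genes fell in 7 of 15 cases and rose in 1 (7 and 2 adjusted over the list alone; camera adjusted p = 0.0157, adjusted p = 0.184 with an estimated correlation). ELOVL6, which encodes a fatty acid elongase, had -0.68 ± 0.10. Matrix genes fell in 17 of 35 cases and rose in 3 (18 and 3 adjusted over the list alone). As a list they had camera adjusted p = 2.02e-09, and 0.0036 with an estimated correlation. Those that fell included the lysyl oxidase gene LOXL2 (-1.68 ± 0.09), COL13A1 (-2.59 ± 0.18) and TIMP3, an inhibitor of matrix proteases (-1.97 ± 0.11). ER chaperone genes fell in 11 of 24 cases and rose in 2 (11 and 2 adjusted over the list alone; camera adjusted p = 0.00563, adjusted p = 0.37 with an estimated correlation). Luminal epithelial markers fell in 7 of 15 cases (7 adjusted over the list alone; camera adjusted p = 0.00102, adjusted p = 0.153 with an estimated correlation), among them the transcription factor gene SPDEF (-2.58 ± 0.25). Fibroblast and endothelial markers fell in 5 of 9 cases (6 adjusted over the list alone; camera adjusted p = 0.00227, adjusted p = 0.0803 with an estimated correlation), among them the growth factor receptor gene PDGFRB (-2.37 ± 0.39). Ribosomal protein genes (57 tested, 1 higher and 1 lower, camera adjusted p = 0.753), respiratory chain genes (38 tested, 3 lower, camera adjusted p = 0.269) and the cholesterol synthesis list (26 tested, 2 higher and 7 lower, camera adjusted p = 0.167) had no list call.

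At 24 h MMS changed 4524 genes, 2324 higher and 2200 lower, of which 149 rose and 805 fell by at least 2-fold, and 15 of 26 lists passed camera's test (1 with an estimated correlation, the matrix list). The count was 6895 with the culture as a block, 688 with the lane as a term (all 4524 genes kept their sign) and 2863 when only the libraries of the 2 groups entered the fit. Without replicate 1 of the 24 h MMS group it was 2481.

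The effect of MMS at 24 h was compared with that at 8 h to ask how the response moved with time. Part of the stress genes had fallen back, and the difference was -2.62 ± 0.16 for HSPA5, -2.72 ± 0.17 for SESN2, -2.23 ± 0.31 for ATF3, -1.65 ± 0.24 for DDIT3 and -2.87 ± 0.29 for HMOX1. ER chaperone genes were lower in 14 of 24 cases (16 adjusted over the list alone), with a median difference of -0.62 (camera adjusted p = 1.71e-30, adjusted p = 0.0434 with an estimated correlation). ATF4 list genes were lower in 15 of 36 cases (16 adjusted over the list alone; camera adjusted p = 7.63e-17, adjusted p = 0.0809 with an estimated correlation), and NRF2 targets in 9 of 28 (10 adjusted over the list alone; camera adjusted p = 5.71e-09, adjusted p = 0.0836 with an estimated correlation). Heat shock genes did not differ as a list, with 1 higher and 3 lower of 24 and a median of 0 (1 and 3 adjusted over the list alone; camera adjusted p = 0.607). HSPA6 (-0.49 ± 1.09, adjusted p = 0.836) and NQO1 (0.01 ± 0.15, adjusted p = 0.974) did not pass. The autophagy list had 8 genes lower and 3 higher (11 and 5 adjusted over the list alone; camera adjusted p = 0.0228, adjusted p = 0.29 with an estimated correlation). The chemokine genes CXCL2 (-2.77 ± 0.34) and IL8 (-2.28 ± 0.35), the hypoxia-regulated VEGFA (-1.59 ± 0.24) and IL6 (-1.50 ± 0.29) were lower too. TOP2A, PDE4B and CCND1, which had fallen at 8 h, differed by 1.20 ± 0.19, 2.35 ± 0.31 and 1.11 ± 0.12, and the adhesion glycoprotein gene THBS1 by 1.63 ± 0.16. Part of the THBS1 difference lay in the controls, where its level was lower at 24 h than at 8 h (below). DUSP6 (0.21 ± 0.13, adjusted p = 0.366) and MDM2 (0.16 ± 0.12, adjusted p = 0.443) did not pass, and CDKN1A had -1.15 ± 0.76 (adjusted p = 0.398, block 0.000145).

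The MMS effect differed with time at 1339 genes, 670 with a higher value at 24 h and 669 with a lower one. Scaling by total counts gave 943 and 599, size factors of the DESeq2 type 522 and 755 and DESeq2 690 and 922, so the balance between directions turned with the scaling. Of the genes called at each time, 906 were higher at both (312 for independent lists, Fisher's exact p = 3.7e-270) and 997 lower at both (287 for independent lists). In opposite directions 128 were called, and Pearson's r of the effects across genes, which are not independent replicates, was 0.548. The count of 1339 became 3712 with the culture as a block, 798 with only the libraries compared, and 1612 by DESeq2. With the lane as a term edgeR called 0 (594 at unadjusted p under 0.05), with the same sign at all 1339 genes. It was 640 and 889 without replicates 1 and 2 of the 8 h controls, 796 and 671 without those of 8 h MMS, 891 without replicate 2 of the 24 h controls and 569 without replicate 1 of 24 h MMS.

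Untreated cells at 24 h differed from those at 8 h at 151 genes, 76 higher and 75 lower (93 and 50 when scaled by total counts, 73 and 47 with size factors of the DESeq2 type). The 2 groups shared no lane, so time and lane cannot be told apart. DDIT4 was higher (1.47 ± 0.22), and ASNS, the asparagine synthetase gene, was lower (-1.57 ± 0.25), as were the chaperone gene HSPA8 (-0.72 ± 0.08), RRM2 (-0.43 ± 0.08) and THBS1 (-1.01 ± 0.12). In the ATF4 list 6 genes were lower and 1 was higher (23 and 1 adjusted over the list alone; camera adjusted p = 7.4e-15, adjusted p = 0.162 with an estimated correlation). NF-kB and cytokine genes were higher in 4 cases and lower in 1 (7 and 2 adjusted over the list alone; camera adjusted p = 2.29e-05, adjusted p = 0.162 with an estimated correlation), including CSF2 (0.67 ± 0.12). Of the 26 lists 9 passed camera's test between the controls, the ATF4 and NF-kB lists among them, and 0 passed with an estimated correlation. The count of genes was 2014 with the culture as a block and 483 by DESeq2. By edgeR it was 0 with the lane as a term (394 at unadjusted p under 0.05). All 151 genes kept their sign with that term, and the median standard error went from 0.148 to 0.385. The count was also 0 when only the 4 control libraries entered the fit (1546 at unadjusted p under 0.05). It was 0 without replicate 1 or 2 of the 8 h controls or replicate 2 of the 24 h controls (1617, 1637 and 1433 at unadjusted p under 0.05), and 15 without replicate 1 of the 24 h controls.

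**Figure D2:**
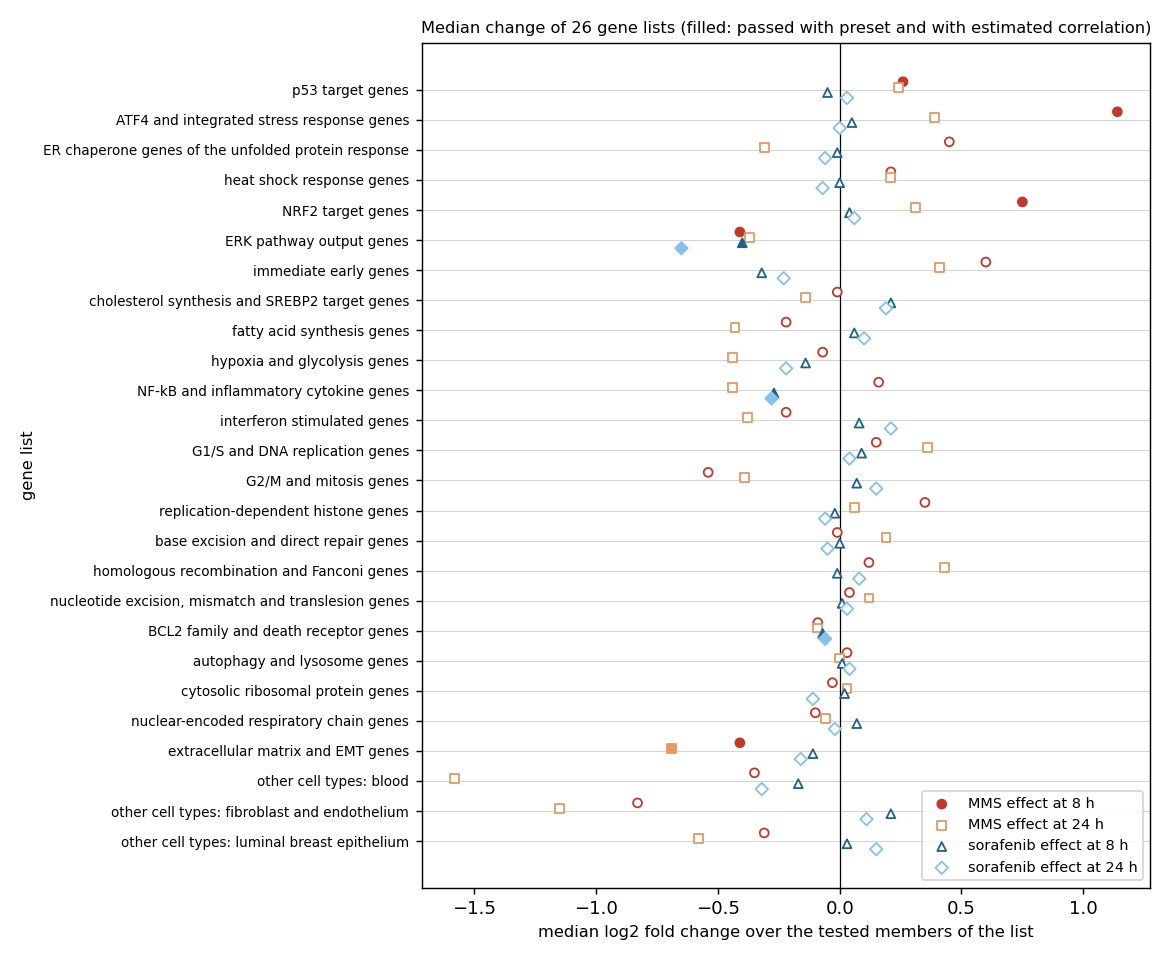
Median log2 fold change (horizontal) of the 26 gene lists (vertical) under MMS or sorafenib alone at 8 and 24 h, with filled symbols where the list passed with both the preset and the estimated correlation. ER chaperone genes had a median of 0.45 after 8 h of MMS and -0.31 after 24 h, and genes that report ERK activity had -0.40 and -0.65 under sorafenib.

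Sorafenib alone at 8 h lowered genes that report ERK activity and a set of inflammatory genes. DUSP6 fell from 347 ± 35.7 to 145 ± 2.83 CPM (-1.26 ± 0.10), and DUSP4, another ERK phosphatase gene (-1.05 ± 0.07), and the feedback inhibitor gene SPRY4 (-0.90 ± 0.11) fell. The interleukin gene IL1B went from 69 ± 0.788 to 10.6 ± 0.407 CPM (-2.70 ± 0.29). CSF3, which encodes a granulocyte growth factor (-2.77 ± 0.17), NOX5 (-3.31 ± 0.39) and IL1A (-1.93 ± 0.26) fell as well. Genes that rose included ATOH8 (3.22 ± 0.45) and ID3 (1.48 ± 0.24), both known targets of BMP signalling, and TGFB2, a TGF-beta ligand gene (0.77 ± 0.14). In the ERK list 5 of 23 genes fell (13 adjusted over the list alone; camera adjusted p = 6.27e-44), in the NF-kB and cytokine list 5 of 31 (11 adjusted over the list alone; camera adjusted p = 1.1e-19). In the BCL2 family and death receptor list 2 of 26 fell, the survival gene BCL2A1 (-2.06 ± 0.27) and the death receptor gene TNFRSF10B (-0.36 ± 0.07; 6 adjusted over the list alone; camera adjusted p = 0.000606). These 3 lists, in that order, also passed with an estimated correlation (adjusted p = 0.000112, 0.00232 and 0.0224). They share members: BCL2A1 and BIRC3 are in both the NF-kB and the BCL2 family list, and LIF is in both the ERK and the NF-kB list. The BCL2 family list had a median of -0.07, and its call is not separate from that of the NF-kB list. Immediate early genes had a median of -0.32, with FOS at -1.92 ± 0.35 (1 lower, 4 adjusted over the list alone; camera adjusted p = 5.3e-08, adjusted p = 0.18 with an estimated correlation). Cholesterol synthesis genes had a median of 0.21 (camera adjusted p = 5.89e-08, adjusted p = 0.209 with an estimated correlation) with no single gene called, SREBF2 being closest (0.34 ± 0.09, adjusted p = 0.222, block 0.0233). CDKN1A had -1.17 ± 0.55 (adjusted p = 0.707, block 1.6e-05).

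At the 24 h time point ERK and inflammatory genes were lower under sorafenib as well. DUSP6 stood at 113 ± 4.95 CPM against 419 ± 3.01 in controls (-1.89 ± 0.10), and SPRY4 fell (-1.19 ± 0.11). IL1B went from 138 ± 29.7 to 18 ± 2.61 CPM (-2.93 ± 0.28), and CSF3 (-3.02 ± 0.16) and the collagenase gene MMP1 (-2.86 ± 0.52) fell. CDH1, which encodes E-cadherin, rose by 2.94 ± 0.59, ATOH8 by 2.68 ± 0.41 and ID3 by 1.44 ± 0.25. In the ERK list 10 of 23 genes fell (20 adjusted over the list alone; camera adjusted p = 1.48e-67), in the NF-kB and cytokine list 8 of 31 (14 lower and 1 higher adjusted over the list alone; camera adjusted p = 3.26e-23). In the BCL2 family and death receptor list 4 of 26 fell, including the survival gene MCL1 (-0.42 ± 0.07; 7 adjusted over the list alone; camera adjusted p = 2.09e-05). These 3 lists, in that order, passed with an estimated correlation as well (adjusted p = 2.55e-05, 0.00109 and 0.00859). Cholesterol synthesis genes had a median of 0.19 (6 higher adjusted over the list alone; camera adjusted p = 9.7e-07, adjusted p = 0.241 with an estimated correlation). Interferon-stimulated genes had 0.21 (camera adjusted p = 2.09e-05, adjusted p = 0.19 with an estimated correlation) and G2/M genes 0.15 (2 higher adjusted over the list alone; camera adjusted p = 1.13e-07, adjusted p = 0.36 with an estimated correlation), with no single member called over all genes. Values of ATF3 (0.17 ± 0.23, adjusted p = 0.971), DDIT3 (-0.05 ± 0.17, adjusted p = 0.997), HMOX1 (-0.28 ± 0.21, adjusted p = 0.844) and IL6 (0.13 ± 0.20, adjusted p = 0.979) did not pass, and CDKN1A had -1.27 ± 0.55 (adjusted p = 0.541, block 6.86e-06).

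Sorafenib changed 65 genes at 8 h (17 higher, 48 lower) and 125 at 24 h (36 higher, 89 lower), and 13 were higher and 36 lower at both times (0.04 and 0.31 for independent lists, Fisher's exact p = 4.39e-32 and 1.56e-72). The counts were 710 and 1019 with the culture as a block, 167 and 286 by DESeq2 and 5 and 7 with only the libraries compared. With the lane as a term they were 1 and 1, with the same sign at all 65 and all 125 genes. Without replicate 1 or 2 of the 8 h controls the first count was 11 or 13 and without those of 8 h sorafenib 4 or 19. The second was 52 or 29 without those of the 24 h controls and 10 or 78 without those of 24 h sorafenib.

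To ask whether sorafenib altered the response to MMS, the MMS effect was measured again among sorafenib-treated cells. At 8 h the leading genes were HMOX1 (3.63 ± 0.21), CHAC1 (3.52 ± 0.34) and ATF3 (3.42 ± 0.23) among those that rose, and PDE7B (-3.82 ± 0.74), PDE4B (-3.43 ± 0.25) and CCL2 (-3.37 ± 0.73) among those that fell. In the ATF4 list 30 of 36 genes rose (33 adjusted over the list alone; camera adjusted p = 3.83e-42), in the ER chaperone list 15 of 24 (18 adjusted over the list alone; camera adjusted p = 1.59e-16). In the NRF2 list 16 of 28 rose (18 adjusted over the list alone; camera adjusted p = 8.04e-21) and in the G2/M list 37 of 43 fell (39 adjusted over the list alone; camera adjusted p = 1.33e-28). All 4, in that order, passed with an estimated correlation (adjusted p = 0.0119, 0.0432, 0.0124 and 0.0432). VEGFA rose by 1.10 ± 0.17, GDF15, a stress-induced cytokine gene, by 2.52 ± 0.34, and CSF3 by 1.52 ± 0.17. CDKN1A had 1.72 ± 0.56 (adjusted p = 0.0503, block 1.38e-08) and MDM2 0.22 ± 0.08 (adjusted p = 0.0764, block 0.023). The autophagy list had 10 genes higher and 3 lower (10 and 4 adjusted over the list alone; camera adjusted p = 0.0615, and 0.0315 with the culture as a block). Its median (-0.02) lay below 0, while its mean (0.17) and camera's direction lay above. Histone genes of the replication-dependent class had no called member among 17 tested and a median of 0.16 (camera adjusted p = 0.862), and blood cell markers had 1 of 5 higher, CD8A (1.09 ± 0.31, camera adjusted p = 0.772).

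At 24 h of MMS with sorafenib, HSPA6 (4.44 ± 0.79), ARC (3.72 ± 0.61) and EGR1 (3.56 ± 0.55), an immediate early transcription factor gene, rose most, and ASB2 (-6.63 ± 0.58), SPTSSB (-4.76 ± 1.35) and UBD, a ubiquitin-like protein gene induced by cytokines (-4.31 ± 0.83), fell most. In the homologous recombination and Fanconi list 17 of 35 genes rose and 1 fell (19 and 1 adjusted over the list alone; camera adjusted p = 0.000306, adjusted p = 0.344 with an estimated correlation). Interferon-stimulated genes fell in 15 of 34 cases (15 adjusted over the list alone; camera adjusted p = 3.04e-05, adjusted p = 0.193 with an estimated correlation). Cholesterol synthesis genes fell in 11 of 26 cases and rose in 1 (12 and 2 adjusted over the list alone; camera adjusted p = 0.00323, adjusted p = 0.396 with an estimated correlation). The regulators INSIG1 (-1.17 ± 0.12) and SREBF2 (-0.78 ± 0.09) and the enzyme gene HMGCS1 (-0.92 ± 0.17) fell. Matrix genes fell in 15 of 35 cases, such as COL5A1 (-1.98 ± 0.14), and rose in 3 (17 and 3 adjusted over the list alone). Their camera adjusted p was 2.39e-06, and 0.0126 with an estimated correlation. IL6 fell (-1.42 ± 0.21), and DUSP6 had -0.11 ± 0.10 (adjusted p = 0.411).

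Under sorafenib MMS changed 3428 genes at 8 h (1772 higher, 1656 lower) and 5235 at 24 h (2727 higher, 2508 lower). Size factors of the DESeq2 type gave 1654 and 1746 at 8 h and 2496 and 2658 at 24 h, and total counts 2010 and 1516 and 2971 and 2367, so which direction held more genes turned with the scaling. For MMS alone it turned as well, with 1827 and 1943 at 8 h by total counts and 2141 and 2313 at 24 h by size factors of the DESeq2 type. At 8 h 1365 genes rose and 1257 fell both without and with sorafenib (238 and 216 for independent lists), with Pearson's r = 0.798 across genes. At 24 h 1985 rose and 1869 fell in both (453 and 395 for independent lists), with r = 0.874. The base-10 logarithms of the 1-sided Fisher's exact p were -1057.9, -958, -1378.9 and -1374.6, and no gene was called in opposite directions at either time. Fisher's exact test takes genes as independent, so its p values here and elsewhere do not measure the spread between cultures. The counts of shared genes were 2191 and 2195 at 8 h and 3052 and 2887 at 24 h with the culture as a block. The count of 3428 was 5617 with that block, 1977 with only the libraries compared, and 1945 without replicate 1 of 8 h sorafenib. With the lane as a term edgeR called 0 (975 at unadjusted p under 0.05), with the same sign at 99.6% of the genes. The count of 5235 was 1341 with the lane term, 3275 without replicate 1 of 24 h sorafenib and 3313 without replicate 2 of 24 h MMS with sorafenib.

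The size of the MMS effect was compared at genes called in the mean of the 2 MMS effects, 5543 genes at 8 h (2818 higher, 2725 lower) and 7138 at 24 h (3740 higher, 3398 lower). At 24 h DESeq2 gave 3387 and 3495, and size factors of its type in edgeR 3459 and 3551. Which direction held more genes thus turned with the scaling at 24 h. At 8 h it did not turn in edgeR, with 2794 and 2756 by size factors of the DESeq2 type and 2936 and 2667 by total counts. DESeq2, which differs in its test as well, gave 2735 and 2739 at 8 h. Among the largest of these averages were those of ATF3 at 8 h (3.45 ± 0.16) and of ARC (4.44 ± 0.42) and ASB2 (-5.21 ± 0.34) at 24 h, and CDKN1A passed at 8 h (1.60 ± 0.39, adjusted p = 0.00909). With the lane as a term the counts were 0 by edgeR (1181 at unadjusted p under 0.05, 95.7% with the same sign) and 2445. The slope of the effect with sorafenib against that without was 0.946 at 8 h (0.973 and 0.932 in the 2 cultures) and 1.025 at 24 h (0.968 and 1.111), and the effect was larger with sorafenib at 44% and 62.4% of the genes. The difference between cultures in the slope at 24 h was larger than its distance from 1.

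**Figure D3:**
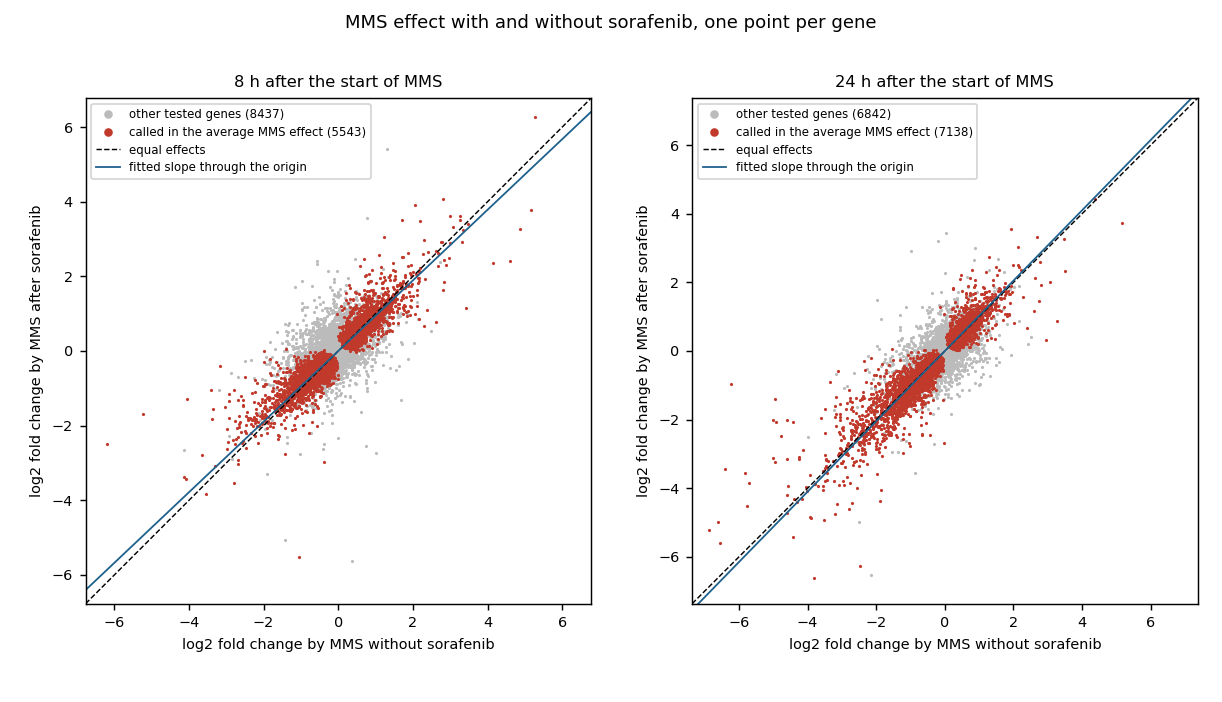
Effect of MMS without sorafenib (horizontal, log2 fold change) against that with sorafenib (vertical) for every tested gene at 8 h (left) and 24 h (right), with genes called in the mean of both effects in red, equal effects dashed and the fitted slope solid. The points lie along the line of equality, with a slope of 0.946 at 8 h and 1.025 at 24 h.

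The difference between the MMS effects with and without sorafenib was then tested gene by gene, and DUSP6 came closest to passing. At 8 h edgeR called 0 genes (505 at unadjusted p under 0.05, 1 by DESeq2, 14 with the culture as a block). It called 34 without replicate 2 of the 8 h group given both agents. At 24 h edgeR called 0 (279 at unadjusted p under 0.05, 2 by DESeq2, 6 with the block, 1 when scaled by total counts and 1 with no filter on low counts). DUSP6 had a difference of 0.98 ± 0.13 at 24 h (adjusted p = 0.11, block 8.03e-05): MMS alone left it at 197 ± 20.3 CPM, sorafenib alone at 113 ± 4.95 and both at 105 ± 0.493. At 8 h its difference was 0.58 ± 0.13 (adjusted p = 1, block 0.0333), and that of the interferon-stimulated gene XAF1 was 1.55 ± 0.37 (adjusted p = 1, block 0.0445). Genes that report ERK activity had a median difference of 0.33 at 24 h (camera adjusted p = 1.07e-16, adjusted p = 0.00443 with an estimated correlation; 3 of 23 higher adjusted over the list alone). With MMS alone at 24 h that list had a median of -0.37 (3 higher, 10 lower, 3 and 11 adjusted over the list alone; camera adjusted p = 1.68e-05, adjusted p = 0.0803 with an estimated correlation). With sorafenib present it had -0.04 and did not pass (5 higher, 6 lower, 5 and 7 adjusted over the list alone; camera adjusted p = 0.307). Hypoxia and glycolysis genes had 0.21 (camera adjusted p = 3.89e-05) and cholesterol synthesis genes -0.18 (camera adjusted p = 3.68e-06) at 24 h, both with adjusted p = 0.424 with an estimated correlation. G2/M genes had -0.10 (camera adjusted p = 3.89e-05, adjusted p = 0.606 with an estimated correlation) and ER chaperone genes 0.12 (camera adjusted p = 0.00122, adjusted p = 0.591 with an estimated correlation). Ribosomal protein genes had 0.07 (camera adjusted p = 0.0195, adjusted p = 0.874 with an estimated correlation) and fatty acid synthesis genes -0.13 (camera adjusted p = 0.029, adjusted p = 0.424 with an estimated correlation). At 8 h the interferon-stimulated list had 0.20 (camera adjusted p = 0.00142, adjusted p = 0.585 with an estimated correlation), ERK genes 0.11 (camera adjusted p = 0.00142, adjusted p = 0.459 with an estimated correlation) and G2/M genes -0.09 (camera adjusted p = 0.01, adjusted p = 0.915 with an estimated correlation). Adjusted over the list alone, 1 interferon-stimulated and 1 ERK gene were higher at 8 h, and 0 genes passed in the other lists of the preceding 4 sentences. Lists that passed only with the block were immediate early (0.0253), hypoxia (0.0414) and histone genes (0.0418) at 8 h, and heat shock (0.0351) and histone genes (0.000422) at 24 h. With an estimated correlation and no block they had adjusted p = 0.915 for each at 8 h, 0.424 for heat shock and 0.844 for histone genes.

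Among MMS-treated cells, part of the genes called lower with sorafenib alone were called lower as well. The others are not shown to respond differently under MMS, as the test of the interaction by edgeR called 0 genes at either time. At 8 h IL1B (-3.32 ± 0.30), CSF3 (-1.82 ± 0.15), DUSP4 (-0.75 ± 0.07) and DUSP6 (-0.69 ± 0.10) fell, as did the immediate early genes FOS (-1.86 ± 0.29), DUSP1 (-1.01 ± 0.16) and ARC (-3.48 ± 0.47) and the stromelysin gene MMP10 (-3.25 ± 0.53). XAF1 (1.97 ± 0.27), ID1 (1.87 ± 0.32) and ID3 (1.76 ± 0.24) rose. In the ERK list 5 of 23 genes fell (11 adjusted over the list alone; camera adjusted p = 2.06e-14) and in the NF-kB and cytokine list 8 of 31 (15 lower and 3 higher adjusted over the list alone; camera adjusted p = 2.54e-15), and both lists passed with an estimated correlation. Immediate early genes fell in 4 of 30 cases (12 adjusted over the list alone; camera adjusted p = 5.67e-13, adjusted p = 0.0998 with an estimated correlation). Luminal epithelial markers had a median of 0.11 (camera adjusted p = 0.0273, 0.05 with the block, and adjusted p = 0.388 with an estimated correlation). At 24 h 14 genes passed, 13 of them lower, among them IL1B (-3.08 ± 0.30), IL1A (-2.21 ± 0.27), CSF3 (-2.13 ± 0.16), DUSP4 (-0.99 ± 0.07), DUSP6 (-0.90 ± 0.10) and the plasminogen activator gene PLAT (-1.26 ± 0.19), and SEL1L3 was the one that rose (1.06 ± 0.15). The ERK list had 3 genes lower (8 adjusted over the list alone; camera adjusted p = 4.87e-35) and the NF-kB and cytokine list 3 (11 adjusted over the list alone; camera adjusted p = 1.95e-30), and both passed with an estimated correlation. The early response gene IER3 had -0.94 ± 0.19 (adjusted p = 0.126, block 8.34e-07) and the epithelial factor gene ELF3 2.05 ± 0.51 (adjusted p = 0.296, block 0.014).

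The 8 h count was 82 (31 higher, 51 lower, and 43 and 41 when scaled by total counts). Of these, 8 higher and 22 lower were also called in the same direction without MMS, which is 22 of the 48 genes lowered there (0.04 and 0.18 for independent lists, Fisher's exact p = 5.24e-18 and 2.92e-43). At 24 h 10 genes were lower both with and without MMS, which is 10 of 13 and 10 of 89 (0.08 for independent lists, Fisher's exact p = 1.83e-20). The 2 counts were 1374 and 277 with the culture as a block, 339 and 81 by DESeq2 and 36 and 4 with only the libraries compared. With the lane as a term edgeR called 0 and 0 (223 and 157 at unadjusted p under 0.05). All 82 and all 14 genes kept their sign with that term. At 8 h the groups compared shared no lane, so sorafenib and lane cannot be told apart there. Leaving out 1 library gave 10 and 12 (replicates 1 and 2 of 8 h MMS), 17 and 658 (replicates 1 and 2 of both agents at 8 h), and at 24 h 7 and 4 (MMS) and 3 and 3 (both agents).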

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

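These results were singled out because an effect differed by test between groups, and all of these tests were chosen before their values were seen. The MMS effect differed between 24 and 8 h at 1339 genes by edgeR's test of the difference. That is 9.6% of the 13980 tested genes, and with the lane as a term edgeR called 0. Among 37 genes named for the MMS effect at either time, 15 passed that test. These 37 include the largest rises and falls at either time in the same libraries, a choice that favours a difference between times. The number that passed is therefore no support for a change with time. The difference was negative for NOX5 (-3.72), KRTAP4-8 (-3.37), SYT12 (-3.2), HMOX1 (-2.87), CHAC1 (-2.83), ADM2 (-2.73), VIPR1 (-2.43), CYTH4 (-2.32), ATF3 (-2.23), OSGIN1 (-1.93), DDIT3 (-1.65), IL6 (-1.5) and HMGCS1 (-0.85). It was positive for ASGR1 (2.22) and PDE4B (2.35). ER chaperone genes had a median difference of -0.62 between the MMS effects at 24 and 8 h, and genes that report ERK activity a median difference of 0.33 between the MMS effects with and without sorafenib at 24 h. Both lists passed camera's test with the preset and the estimated correlation.

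The number of genes called in the mean MMS effect could come from chance, which was weighed by regrouping the 8 libraries of each time into 4 and 4 in all 35 ways. At 8 h 1 split reached the count of the treatment split (4890 genes in a fit with 2 groups), that split itself, and the highest other count was 236. At 24 h 1 of 35 splits reached it as well (6968 genes), and the highest other count was 166. At both times the highest other split was the one by culture. The treatment split ranked highest of 35 at each time, which makes chance regrouping of libraries an unlikely source of the MMS calls. Other splits left the MMS effect in their residual spread, which lowers their counts, so the gap between counts does not measure chance. The splits do not bear on the lane, which was confounded with treatment at 8 h.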

How the results depend on the processing

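All settings were chosen before the results were seen. With the culture as a block, counts of called genes were 6100 (MMS 8 h), 6895 (MMS 24 h), 710 and 1019 (sorafenib), 5617 (MMS with sorafenib 8 h), 1374 and 277 (sorafenib with MMS), 14 and 6 (interaction), 3712 (MMS 24 against 8 h) and 2014 (controls). Genes shared by the MMS effects without and with sorafenib were 2191 and 2195 at 8 h and 3052 and 2887 at 24 h with that block. Where it changed the call of a gene printed with its standard error or of a list printed with its adjusted p, the report gives its value. With the lane as a term, edgeR's counts were 0 (816 unadjusted), 688, 1, 1, 0 (975), 1341, 0 (223), 0 (157), 0 (594), 0 (394), 0 (1181) and 2445 in the order MMS, sorafenib, MMS with sorafenib, sorafenib with MMS, MMS by time, controls, mean MMS. IFIT2 (0.13 for MMS, 0.02 for the mean), ACSS2 (0.08) and ACSL3 (0.07) turned sign at 8 h with that term, and the cause was not tested. With only the libraries compared the counts were 2863 (MMS 24 h), 5 and 7 (sorafenib), 1977 (MMS with sorafenib 8 h), 36 and 4 (sorafenib with MMS), 798 (MMS by time) and 0 (controls, 1546 unadjusted). DESeq2 gave 167 and 286, 339 and 81, 1 and 2 (interaction) and 483 (controls), and total counts and no filter gave 1 each for the interaction at 24 h. Leaving out 1 library gave 2372 to 2631 (MMS 8 h), 2481 to 3562 (24 h), 4 to 19 and 10 to 78 (sorafenib), 1945 to 2985 and 3275 to 3841 (MMS with sorafenib), 10 to 658 and 3 to 7 (sorafenib with MMS), 0 to 34 (interaction 8 h), 569 to 969 (MMS by time) and 0 to 15 (controls). Genes with a larger MMS effect with sorafenib at 8 h made up 47.6% with total counts and 38.6% among the 500 genes of smallest p. Of 147 list calls, 34 held with an estimated correlation, as follows. In the sorafenib effects these were ERK and NF-kB genes in all 4 and BCL2 family genes in all but that with MMS at 8 h. In the MMS effects and their means they were matrix genes at both times and p53, ATF4 and NRF2 genes at 8 h. ERK genes held for MMS alone and the mean at 8 h and for the interaction at 24 h, ER chaperone and G2/M genes for MMS with sorafenib and the mean at 8 h, and ER chaperone genes for MMS by time.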

Other observations

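Among the tests of this part, only those of small nucleolar RNAs were chosen after the result was seen. MMS lowered genes of long genomic span. Among 12827 protein-coding genes, the 2566 longest (median 170 kb) had a median of -0.229 under MMS at 8 h (-0.213 and -0.232 in the cultures), and 25.8% of them fell while 5.3% rose. In the 2566 shortest (median 5.8 kb) the median was -0.022, and 9.2% fell while 12.5% rose. Between them lay groups of median span 16.5, 33.4 and 66.3 kb, with medians of 0.015, 0.038 and -0.005. In these groups 10.3, 10.2 and 12.4% fell while 18.8, 18.6 and 14.1% rose. The longest genes had -0.237 at 24 h, and with sorafenib present -0.278 at 8 h and -0.305 at 24 h. With sorafenib present at 8 h the shorter groups had 0.087, 0.093, 0.065 and -0.023 in order of span. Sorafenib alone gave them 0.007 at 8 h and 0.055 at 24 h.

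The 2 cultures differed at 5710 genes, 2694 higher and 3016 lower in culture 2. By at least 2-fold 267 were higher and 197 lower. The genes named here, from among the largest differences, had the same sign in all 8 pairs. Each culture was 1 unit, so the calls measure how steadily these 2 cultures differed over the 8 pairs, and not how cultures vary. MAGEA12, a cancer-testis antigen gene of a family that shares reads, stood at 24.2 CPM in culture 1 and 0.118 CPM in culture 2, and SERPINB2, a protease inhibitor gene, at 33.7 and 1.97 CPM. LBH, a transcription cofactor gene, stood at 0.897 and 10.4 CPM and MMP9, a gelatinase gene, at 1.68 and 12.2 CPM. Per the labels, titles spell the line MDA231 for replicate 1 and MDA213_2 for replicate 2. Histone genes of the replication-dependent class were higher in culture 2 in 11 of 17 cases (median 1, camera adjusted p = 6.1e-12, adjusted p = 0.193 with an estimated correlation). Ribosomal protein genes were lower in 37 of 57 cases (camera adjusted p = 6.29e-08), respiratory chain genes in 23 of 38 (0.004) and G1/S genes in 20 of 35 (0.049), each with adjusted p = 0.684 with an estimated correlation. Immediate early genes were higher in 15 of 30 cases (camera adjusted p = 0.037) and hypoxia genes in 14 of 30 (0.0167), also with adjusted p = 0.684 with an estimated correlation. Principal component 1 (36.6% of variance) separated MMS, component 2 (20.3%) the cultures and component 4 (7.4%) sorafenib.

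Of 89 small nucleolar RNAs tested, 6 rose with MMS at 24 h (median 0.39, 0.03 and 0.65 in the cultures), and 21 rose and 1 fell with sorafenib present (median 0.82, 0.81 and 0.76). Their median also moved without MMS, to -0.53 in controls at 24 against 8 h and to -0.38 under sorafenib at 8 h. Most lie in introns of other genes and their median level was 0.821 CPM, and their reads were not separated from those of their hosts.

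Long genes may have fallen at 8 h because MMS lesions block transcript elongation, which meets more lesions over a longer span. The partial Spearman correlation with span, given transcript length, GC content and mean expression, was -0.217 without sorafenib, the higher of the 2 MMS effects at 8 h, and that prediction was met. Given transcript length the correlation was -0.183 (-0.133 and -0.218 in the cultures), and given GC content -0.223 (-0.216 and -0.212). These values argue against either as the whole cause. The length was that of the longest annotated transcript, so a bias with the length of the transcripts present may not be fully removed. Other properties that go with span, such as RNA half-life, were not tested and could also contribute. Without sorafenib at 8 h the fall lay in the longest genes, and the medians of the shorter groups did not fall steadily with span. The prediction that was met restates the link with span, so it cannot tell a block to elongation from such properties.

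The difference between cultures could be chance or cells of another type. Of 100 splits that part all 8 pairs, 1 reached the real count of 5710, the split by culture itself. The highest other count was 2494, in a split that differed from the real one in 1 pair. The rank of the culture split makes chance an unlikely source. Other splits left the culture difference in their residual spread, which lowers their counts, so the gap between counts does not measure chance. Of 5 tested genes of the blood cell list 60% passed in the direction of culture 2, CD68 (100 and 126 CPM), CD14 (2.53 and 5.37 CPM) and CD8A (2.61 and 3.41 CPM), while PTPRC was lower. Of 15 luminal epithelial markers 2 were higher and 6 lower in culture 2, among the latter AGR2 (10 and 3.13 CPM), and of 9 fibroblast and endothelial markers 0 were higher and 3 lower. In the blood cell list of 16, CSF1R did not pass. Its untested members, such as LYZ (7), HBB (1), ITGAM (2), CD3E (2) and MS4A1 (0), had no more than 7 reads in any library. The share of 60% met 1 part of the prediction for admixture. The other part, that the most abundant members of the list lie above 10 CPM, failed at CD14, the next after CD68. Admixture was therefore left undecided. A change within the line or another source of it might also give such differences, and no biological explanation was tested.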
